A study of Mus musculus with 8 samples.

How the data were processed

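The samples were 8 mouse libraries of uterine luminal epithelium on day 4, cut out of frozen sections by laser microdissection and sequenced as RNA. Per the labels, 4 libraries came from normal pregnancy and 4 from pseudopregnancy, a state of hormonal pregnancy without embryos. The sample titles also carry the number 10 or 17, whose meaning the labels do not give, so libraries were grouped by condition and title number into 4 groups of 2 libraries. The tissue field of the labels reads decidua while the cell type field reads epithelium; the protocol describes dissection of luminal epithelium and also names a TRIzol extraction of whole uteri, without saying which library had which. Whether each library came from its own animal is not given in the sources used here.

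The authors deposited 1 table with 54082 gene entries. Its read count columns hold whole numbers, and were deposited without normalization as far as the values show. Per the submitters' processing notes, reads were aligned with STAR to the mm10 build and edgeR was used; the versions, the counting tool, the strand setting and the annotation are not given in the sources used here. The deposited table also holds adjusted signal columns, each close to the count column times 1 factor per library (0.967 to 1.087 over genes with at least 200 counts), and FPKM columns, per the file headers. The authors' fold (ratio) columns and p-value columns describe 4 comparisons of their own, per the file headers, with no adjustment for multiple testing named. Only the count columns entered the tests; the adjusted and FPKM columns served to check units and to derive relative gene lengths, and the authors' folds and p-values were only set beside the results. Library totals ran from 32850740 to 41165334 counts.

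Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 4 groups, which left 20137, and libraries were scaled by TMM factors (0.901 to 1.080). A single quasi-likelihood model (glmQLFit, glmQLFTest) with the 4 groups and no covariate gave 4 residual degrees of freedom, a median prior of 4.12 degrees of freedom, and a biological coefficient of variation of 19.3%. There were 6 contrasts: pregnancy against pseudopregnancy at number 10, at number 17 and averaged over both numbers, the difference between the first and the second of these, and 17 against 10 within pregnancy and within pseudopregnancy. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p below 0.05. Standard errors of log2 fold changes are the log2 fold change divided by the square root of the F statistic. CPM values (counts scaled to a common library total) of single genes are scaled by TMM; summed CPM of marker lists, blastocyst genes and protocadherin genes use the library totals alone. Principal components were computed on log2 CPM with a prior count of 2.

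Before the data were examined, 28 gene lists were fixed. Of these, 18 describe processes: lysosomal hydrolases and membrane proteins, vacuolar ATPase, autophagy, proteasome, TNF and NF-kB response, progesterone response, oestrogen response, receptivity and attachment, interferon-stimulated genes, cell cycle, epithelial junctions, ion and water transport, circadian clock, unfolded protein response, cholesterol synthesis, immediate-early genes, mitochondrially encoded mRNAs and ribosomal proteins. The other 10 hold markers of pan-epithelial, luminal, glandular, stromal, smooth muscle, endothelial, leukocyte, neutrophil, blastocyst and erythroid cells. Lists with at least 3 measured members were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast; camera with an estimated correlation and fry were run beside it. Member counts are given after adjustment over all genes and adjusted over the list alone. Gene families, defined by symbol stems with at least 15 tested members, were tested with Fisher's exact test, two-sided; this was chosen after the data were seen.

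The genes to be named were set by a rule fixed at the same time: at number 17 the 10 called genes with the largest rise and the 10 with the largest fall, and 5 of each for the other contrasts, with a mean of at least 5 CPM in the higher group and, except for the difference of effects, no overlap between the libraries of both sides. Where no gene passed, the 3 genes with the smallest p were named. Up to 4 members with the smallest p were taken from each list, and Tnf, Lif, Pgr, Esr1, Ihh, Areg, Ltf, Muc1, Msx1, Hbegf, Ptgs2, Lamp1, Ctsl and Ctsd were always reported where measured; Tnf was not among the genes tested. Predicted and numbered gene models were counted but not named by this rule.

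Gene coordinates are from GENCODE mouse release 21, on the same assembly as mm10; 52099 gene symbols matched 1 gene there, and 37850 entries had an Entrez number in the deposited table. The scripts were tested on simulated counts built from the means and totals of these libraries. For pregnancy against pseudopregnancy at number 17, over 19702 genes, the fit recovered 6% of 50 genes changed 1.5-fold, 44% of 50 changed 2-fold, and 100% of those changed 4-fold or 8-fold, and 11.3% of the calls were false. Replicates varied beyond counting error, with chi-square per degree of freedom of 21.4 to 53.5 within groups.

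The alternatives fixed in advance were size factors of the relative log expression (RLE) kind, no filter on low counts, a stricter filter of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma voom, the replicate number as a block, a log2 fold change of at least 1, fits of only the 2 groups compared, an additive model of condition and number, and leaving out each library in turn. Removal of Gm26917, offsets that remove each library's trend on gene length, and these offsets together with the block were added after the data were seen. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and exact permutation tests of summed CPM enumerate all splits of the libraries. No library was left out of the reported fits.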

Results

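Gene expression was measured by RNA sequencing in luminal epithelium, the cell layer that lines the uterine cavity, from mouse uteri on day 4 of pregnancy or pseudopregnancy. The 8 libraries form 4 groups of 2, named here pregnancy 10, pregnancy 17, pseudopregnancy 10 and pseudopregnancy 17 after the condition and the number in the sample titles. The library totals were 32850740 and 41165334 counts for pregnancy 10, 33906558 and 33836717 for pregnancy 17, 36588189 and 38429562 for pseudopregnancy 10, and 36025920 and 35560637 for pseudopregnancy 17. Epithelial keratins, junction genes and Epcam dominated the marker genes in every library, with a median of 382 to 487 CPM over the 8 pan-epithelial markers against 6.36 to 15.3 CPM over the 12 stromal markers. The most abundant transcript, Gm26917, a long non-coding RNA model, held 5.46% and 7.31% of the counts in pregnancy 17 and 7.78% to 9.77% in the other 6 libraries. Mitochondrially encoded mRNAs held 1.35% to 1.92% of the counts. CPM values are means ± SD over n = 2 libraries, log2 fold changes carry a standard error (SE), and adjusted p-values of single genes are Benjamini-Hochberg values of edgeR's quasi-likelihood test. Coordinates are on mm10. The p-values measure only the spread between these libraries; if libraries of a group came from the same animal, they are too small.

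The pregnancy 17 libraries stood apart from the other 6. On the first principal component, which held 56.6% of the variance of log2 CPM, they lay at 104 and 74.6, while pseudopregnancy 17 lay at -20.9 and -0.410 and the 4 libraries of number 10 between -41.0 and -35.6. The second component held 12.9%.

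**Figure D1:**
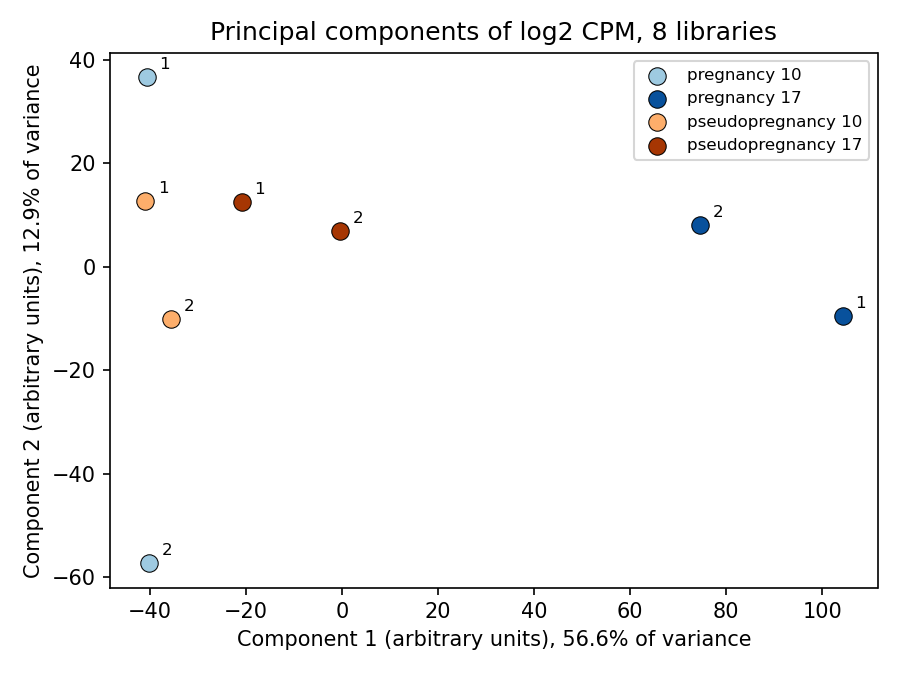
Each point is 1 library, placed by its scores on the first and second principal component of log2 CPM (arbitrary units), and coloured by group. The 2 pregnancy 17 libraries lie at 104 and 74.6 on the first component, and the other 6 lie at or below -0.410.

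The comparison at number 17 asks how the epithelium differs between pregnancy and pseudopregnancy, the state without embryos. Whether blastocysts were in the uterus at number 17 was not tested. Nr4a3, Fga, Sftpd and Lrat are among the genes that were higher in pregnancy 17, and Mc4r and Grk3 among those that were lower. Nr4a3, an orphan nuclear receptor (chromosome 4, 48045153 to 48086447), rose 60.4-fold, from 4.23 ± 0.678 CPM in pseudopregnancy 17 to 256 ± 111 CPM in pregnancy 17. Fga, the fibrinogen alpha chain (chromosome 3, 83026076 to 83033627), rose 94.1-fold to 15.99 ± 2.11 CPM, and Sftpd, the collectin surfactant protein D (chromosome 14, 41172214 to 41185149), rose 57.6-fold to 50.5 ± 24.3 CPM. Lrat, the enzyme that esterifies retinol for storage (chromosome 3, 82892579 to 82903973), rose from 4.29 ± 3.23 to 128 ± 20.3 CPM. In the other direction, Mc4r, the melanocortin 4 receptor (chromosome 18, 66857704 to 66860506), was 22.1-fold lower at 0.420 ± 0.362 CPM in pregnancy 17, and Grk3, a kinase that desensitises G protein-coupled receptors (chromosome 5, 112910482 to 113015791), was 10.5-fold lower.

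By edgeR's test 1986 of 20137 genes differed, 1069 higher and 917 lower in pregnancy, and 1236 of them differed at least 2-fold (822 higher, 414 lower). The log2 fold changes were 5.92 ± 0.59 for Nr4a3 (adjusted p = 0.00389), 6.56 ± 0.48 for Fga (0.00164), 5.85 ± 0.50 for Sftpd (0.00310), 4.90 ± 0.54 for Lrat (0.00542), -4.47 ± 0.57 for Mc4r (0.00721) and -3.39 ± 0.36 for Grk3 (0.00494). The other strongest rises were those of Adm2, Egr3, Steap4, Npnt, Scube2 and Fosb, with log2 fold changes of 4.88 to 6.68. Adm2, a peptide hormone of the adrenomedullin family, had 4 counts in total in pseudopregnancy 17 and varied widely in pregnancy 17 (6.03 ± 6.56 CPM). The other strongest falls were those of Spsb4, Cdh4, Fndc1, Kcnh3, Kbtbd8, Lgalsl, Slc51a and Ccn4, with log2 fold changes of -5.13 to -3.02. The rule for naming genes required both pregnancy 17 libraries to lie on the same side of both pseudopregnancy 17 libraries. That these 20 genes do so is therefore no separate evidence. Without pregnancy 17 replicate 1 the count was 273, without pseudopregnancy 17 replicate 1 it was 68, and without pseudopregnancy 17 replicate 2 it was 679. It was 1047 and 1020 without pseudopregnancy 10 replicate 1 or 2, 805 when only the 2 groups were fitted, and 1236 with a log2 fold change of at least 1.

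**Figure D2:**
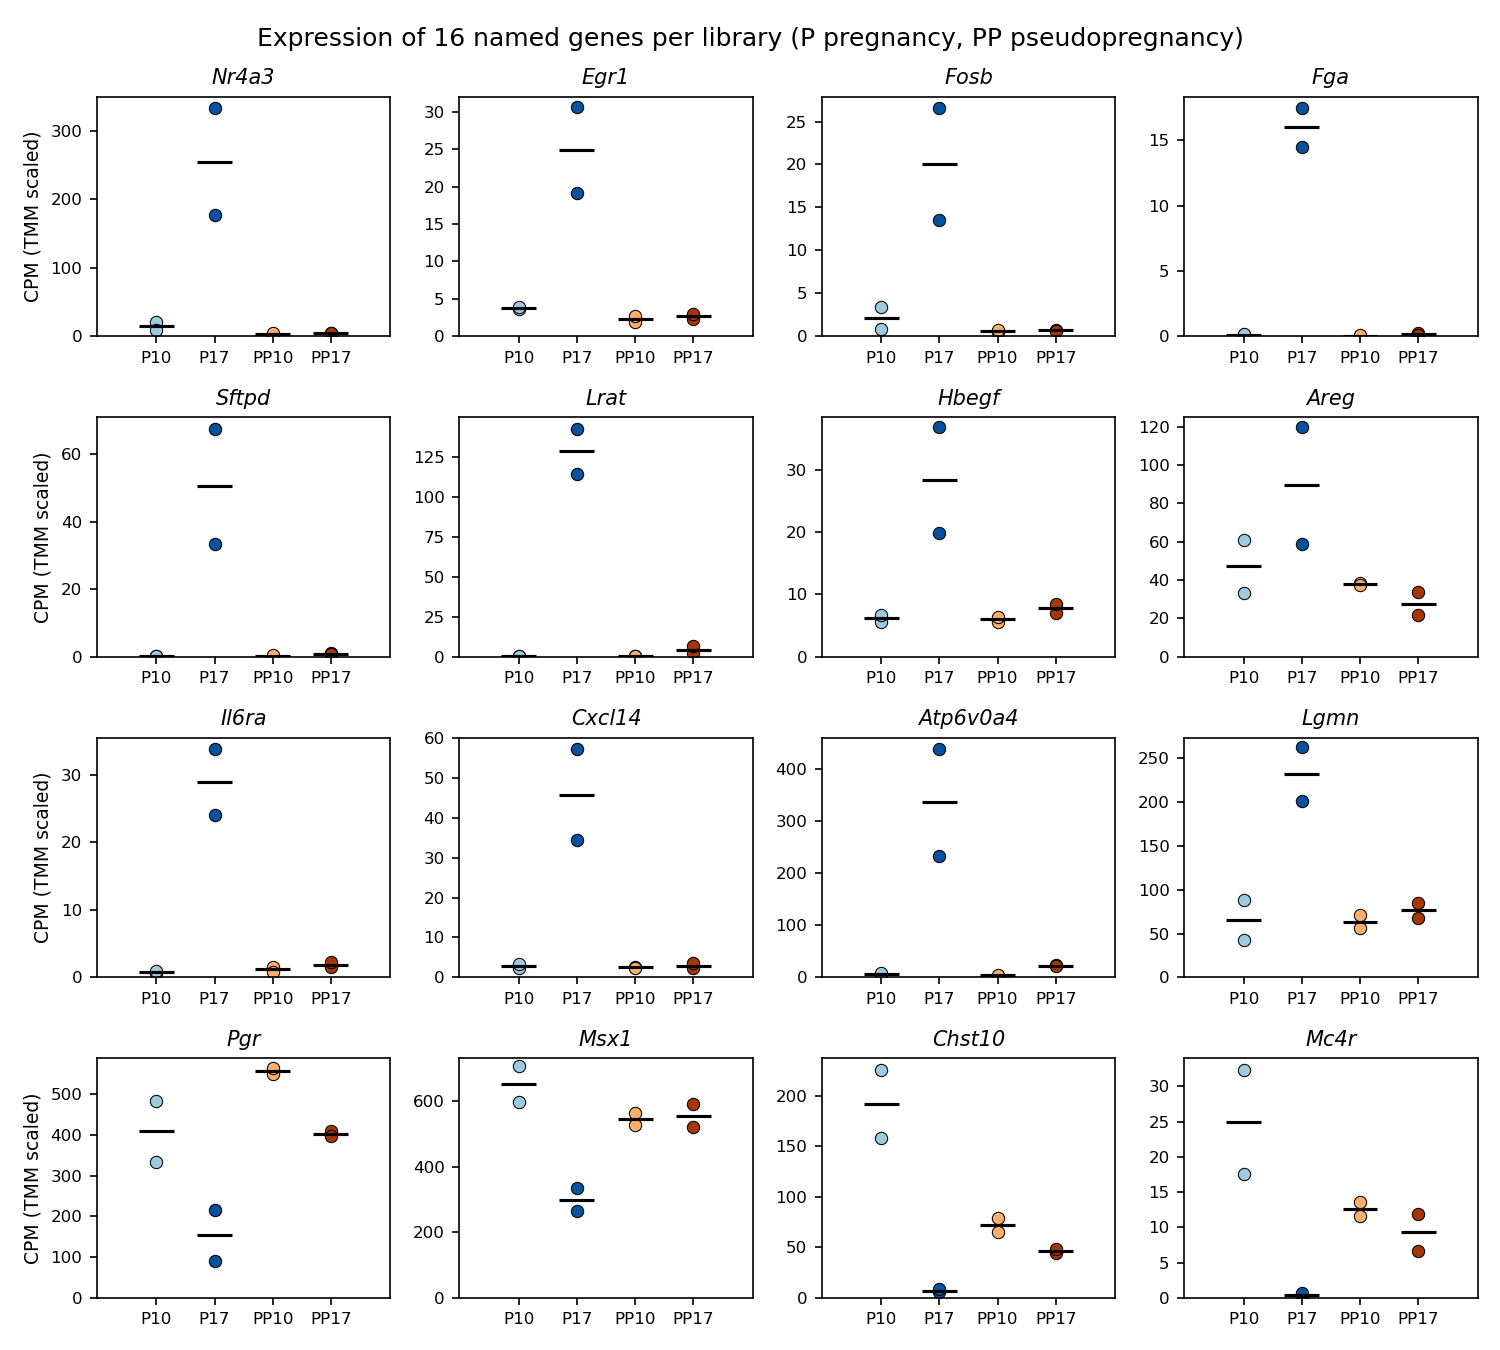
Each panel shows 1 gene, with CPM scaled by TMM on the vertical axis from 0; points are single libraries, lines are group means, P is pregnancy, PP is pseudopregnancy and 10 or 17 is the title number. Nr4a3 reaches a mean of 256 CPM in pregnancy 17 against 4.23 CPM in pseudopregnancy 17, and Chst10 falls from a mean of 192 CPM in pregnancy 10 to 7.04 CPM in pregnancy 17.

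Several immediate-early genes, which cells switch on within minutes of a signal, rose at number 17. Of 15 measured, 7 rose and 1 fell (10 passed when adjusted over the list alone); Fosb rose by 4.88 ± 0.65 on the log2 scale, Nr4a1 by 4.66 ± 0.51, Egr1 by 3.23 ± 0.30 and Fos by 2.64 ± 0.34. Nr4a1 went from 1.64 ± 0.374 to 41.3 ± 16.01 CPM and Fos from 18.3 ± 0.499 to 115 ± 59.8 CPM. Camera at the preset correlation called the list (adjusted p = 2.93e-06); with an estimated correlation the adjusted p = 0.400. Stromal markers had a median log2 fold change of 0.56 in the same comparison (0 of 12 called, 0 adjusted over the list alone, camera adjusted p = 0.277), and their summed CPM was 346 and 210 in pregnancy 17 against 237 and 194 in pseudopregnancy 17.

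Genes of the receptivity and attachment list moved in both directions. Of 21 measured, 6 rose and 3 fell (11 adjusted over the list alone; camera adjusted p = 0.180). Wnt7b, a WNT ligand, rose by 3.09 ± 0.48 on the log2 scale, and Lifr, the receptor of leukaemia inhibitory factor, rose from 234 ± 29.4 to 981 ± 313 CPM (log2 fold change 2.07 ± 0.23). Hbegf, a heparin-binding EGF-like growth factor, rose from 7.78 ± 0.991 to 28.4 ± 12.0 CPM (log2 fold change 1.87, adjusted p = 0.0116). Msx1 and Msx2, homeobox genes of the uterine epithelium, fell: Msx1 from 556 ± 48.4 to 300 ± 49.7 CPM (log2 fold change -0.89, adjusted p = 0.0177) and Msx2 by a log2 fold change of -2.23 ± 0.40.

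The progesterone response list had 3 members that rose and 2 that fell of 8 measured (7 adjusted over the list alone; camera adjusted p = 0.180). Fst, which binds activin, rose by 4.23 ± 0.64 on the log2 scale, Cyp26a1, which breaks down retinoic acid, rose from 95.5 ± 1.22 to 459 ± 173 CPM, and Areg, an EGF-family ligand, rose by 1.69 ± 0.39 (adjusted p = 0.0355). The progesterone receptor Pgr fell from 402 ± 8.84 to 154 ± 88.7 CPM (log2 fold change -1.39, adjusted p = 0.0467), and Gata2 fell from 758 ± 81.2 to 225 ± 140 CPM. In the oestrogen response list 5 of 13 rose and 0 fell (6 adjusted over the list alone), among them Muc4, a membrane mucin (log2 fold change 1.76 ± 0.21), Lcn2 (1.83 ± 0.30) and complement C3 (1.16 ± 0.22). Sprr2g rose by 3.44 ± 0.58, but shares close sequence with its paralogs, so its count is uncertain. Camera called this list at the preset correlation (adjusted p = 0.00433), and with an estimated correlation the adjusted p = 0.805. Log2 fold changes that did not pass were -0.82 for Lif (adjusted p = 0.199), -0.26 for Esr1 (0.232), 0.78 for Ihh (0.107), -0.12 for Ltf (0.938), 0.33 for Muc1 (0.236) and 1.33 for Ptgs2 (0.190).

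The series title names the lysosome, and its genes moved in both directions at number 17. Of 57 lysosomal hydrolases and membrane proteins, 3 rose and 5 fell (11 adjusted over the list alone), with a median log2 fold change of -0.11 and a camera adjusted p = 0.180. Ppt1, a palmitoyl-protein thioesterase, fell from 191 ± 53.3 to 73.5 ± 7.59 CPM, Npc2, a cholesterol transfer protein, fell by a log2 fold change of -0.69 ± 0.12, and Hexa, a hexosaminidase subunit, by -0.65 ± 0.12. Gla, the alpha-galactosidase, rose by 1.28 ± 0.24. Lamp1, Ctsl and Ctsd had log2 fold changes of -0.25 (adjusted p = 0.280), 0.38 (0.454) and -0.08 (0.873); Ctsd, the protease cathepsin D, stood at 8825 ± 141 CPM in pregnancy 17 and 9316 ± 1260 CPM in pseudopregnancy 17.

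Among 20 subunits of the vacuolar ATPase, the proton pump of acidic compartments, 2 rose and 1 fell (5 adjusted over the list alone; camera adjusted p = 0.839). Atp6v0a4, a subunit known from specialised acid-secreting cells, rose 15.2-fold, from 22.04 ± 1.58 to 336 ± 144 CPM (log2 fold change 3.93 ± 0.36, adjusted p = 0.00368). Atp6v0d2 rose from 6.13 ± 0.205 to 28.5 ± 10.2 CPM and Atp6v0a1 fell by a log2 fold change of -0.64 ± 0.16. The list's median, -0.13, and mean, 0.19, differ in sign. Of 29 autophagy genes, 2 rose and 1 fell (6 adjusted over the list alone; camera adjusted p = 0.789): Uvrag rose by 1.45 ± 0.19, Atg14 by 0.77 ± 0.11, and Tfeb, a transcription factor for lysosomal genes, fell by a log2 fold change of -0.93 ± 0.23. The proteasome list had 0 called of 31 (0 adjusted over the list alone; camera adjusted p = 0.789).

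The unfolded protein response list had 3 risen and 1 fallen member of 17 (6 adjusted over the list alone). The transcription factor Xbp1 rose from 107 ± 11.5 to 453 ± 116 CPM, Trib3 by 3.15 ± 0.45 and Asns, asparagine synthetase, by 1.73 ± 0.27 on the log2 scale, while the chaperone gene Hsp90b1 fell by a log2 fold change of -0.67 ± 0.17. Of 20 cholesterol synthesis genes 4 rose and 0 fell (8 adjusted over the list alone), Cyp51 by 1.26 ± 0.26, Msmo1 by 1.05 ± 0.19 and the LDL receptor gene Ldlr by 0.83 ± 0.13. Camera called both lists at the preset correlation (adjusted p = 0.00794 and 0.0217), and with an estimated correlation both had an adjusted p = 0.805. Ion and water transport genes split evenly, with 3 risen and 3 fallen of 12 (8 adjusted over the list alone; camera adjusted p = 0.789): the chloride channel gene Cftr rose by 1.04 ± 0.17, the ubiquitin ligase gene Nedd4l by 1.09 ± 0.24, and the sodium channel subunit gene Scnn1a fell from 74.3 ± 10.5 to 34.9 ± 8.36 CPM. In the circadian clock list 2 rose and 1 fell of 16 (5 adjusted over the list alone; camera adjusted p = 0.839): Per2 rose by 1.15 ± 0.13, Nfil3 by 1.48 ± 0.32, and Bhlhe40 fell by a log2 fold change of -1.07 ± 0.17.

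In the TNF and NF-kB list 2 rose and 0 fell of 21 (5 adjusted over the list alone; camera adjusted p = 0.233), namely Lcn2 and Ier3 (1.69 ± 0.19). The epithelial junction list had 2 fallen members of 19 (5 adjusted over the list alone; camera adjusted p = 0.197), Tjp3 (-1.01 ± 0.19) and Cgn (-0.61 ± 0.12), both of tight junctions. Of 23 cell cycle genes 1 rose (1 adjusted over the list alone; camera adjusted p = 0.789): Top2a, a topoisomerase of dividing cells, from 146 ± 17.7 to 453 ± 43.3 CPM. No member passed, over all genes or over the list alone, among 25 interferon-stimulated genes (median log2 fold change -0.47, camera adjusted p = 0.498), 12 mitochondrially encoded mRNAs (-0.02; 0.789) and 36 ribosomal protein genes (-0.14; 0.197).

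Markers of cell types also moved at number 17. The pan-epithelial keratin Krt19 fell by a log2 fold change of -1.36 ± 0.25, as 1 of 8 markers (4 adjusted over the list alone; camera adjusted p = 0.233). Of 7 luminal markers Met rose by 1.23 ± 0.19 and Msx1 fell (4 adjusted over the list alone; camera adjusted p = 0.789). Of 3 measured glandular markers Foxa2 fell from 1.01 ± 0.0311 to 0.222 ± 0.00468 CPM (1 adjusted over the list alone; camera adjusted p = 0.197). Synpo2, 1 of 7 smooth muscle markers, rose by 0.99 ± 0.13 (2 adjusted over the list alone; camera adjusted p = 0.222), and the smooth muscle markers summed to 102 and 79.1 CPM in pregnancy 17 against 44.2 and 45.1 CPM in pseudopregnancy 17. Synpo2 alone held 92.5 and 72.7 CPM of these sums against 38.6 and 39.7 CPM, and Myh11 went the other way, with 0.826 and 0.828 CPM against 2.08 and 1.88 CPM. Tek, 1 of 8 endothelial markers, rose from 0.472 ± 0.00533 to 2.46 ± 0.738 CPM (1 adjusted over the list alone; camera adjusted p = 0.197), and the endothelial markers summed to 30.6 and 16.7 CPM against 14.2 and 13.4 CPM. Among 11 leukocyte, 3 blastocyst and 3 erythroid markers 0 passed over all genes or over the list alone (camera adjusted p = 0.810, 0.839 and 0.839), and the neutrophil markers, at most 0.4996 CPM in sum, were too few for a test. The median and the mean of the log2 fold changes differed in sign for the cell cycle (-0.05 and 0.07), circadian clock (-0.01 and 0.05) and erythroid lists (-0.06 and 0.01), and camera's direction for the blastocyst markers was down with a median of 0.04.

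**Figure D3:**
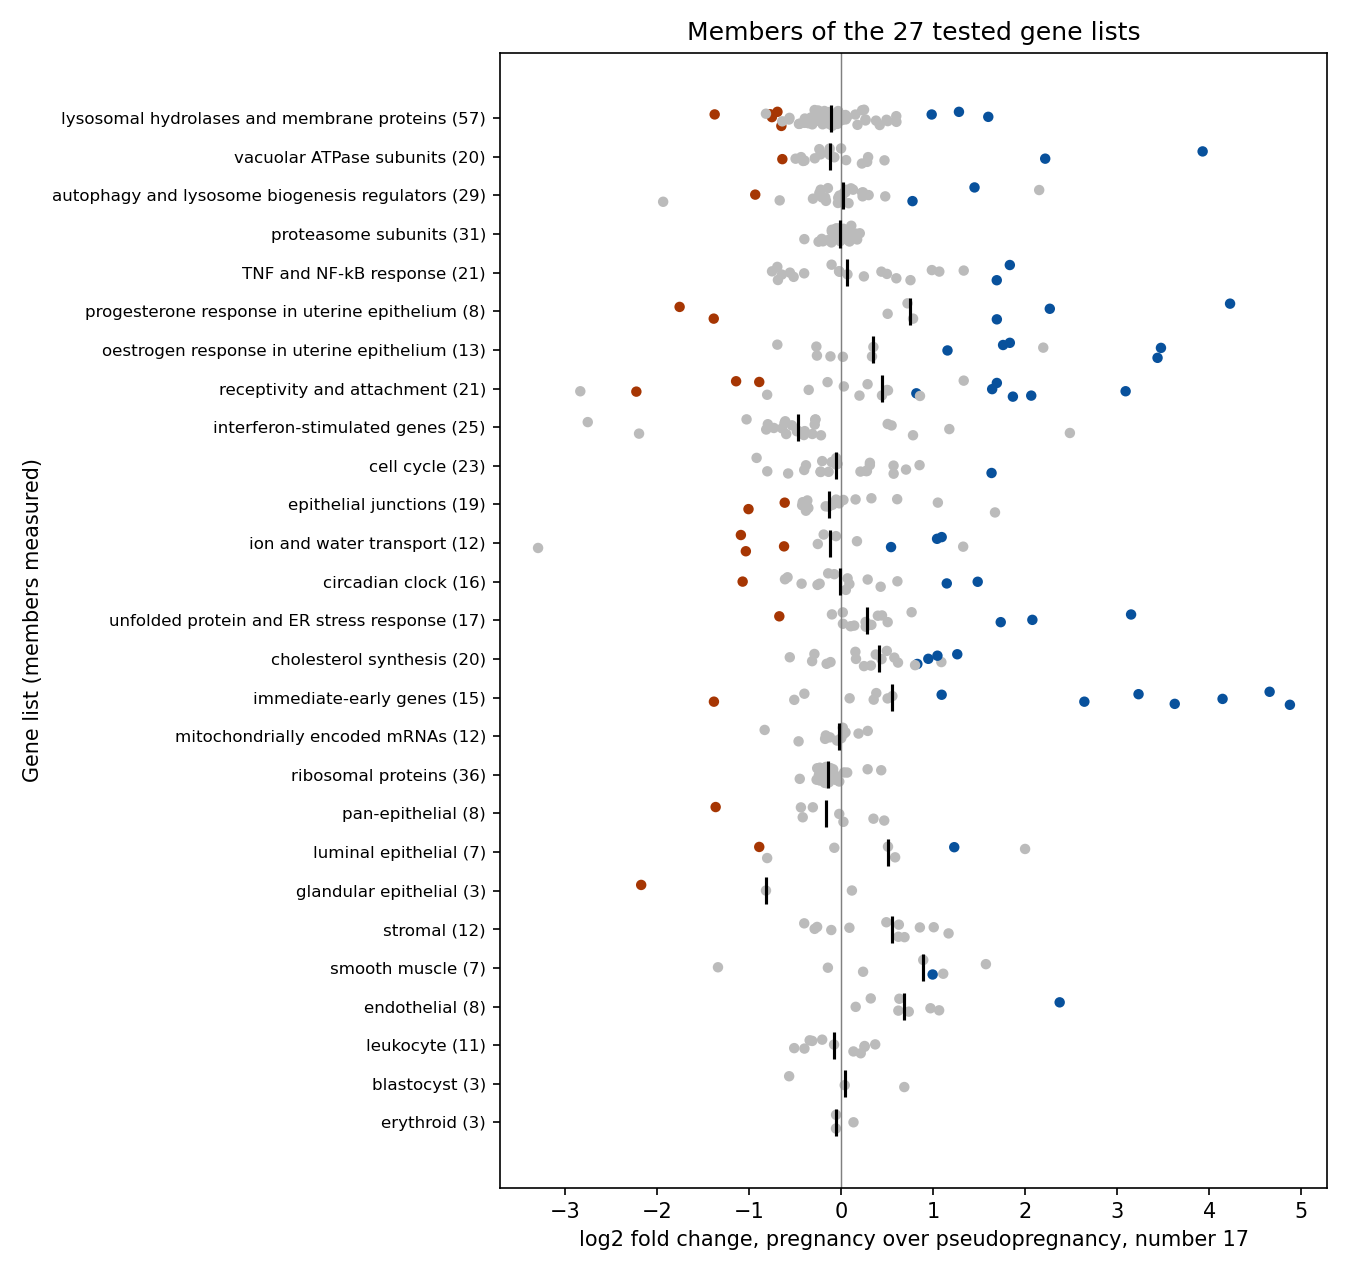
Each point is a gene of 1 of the 27 tested lists, placed by its log2 fold change of pregnancy over pseudopregnancy at number 17; blue points rose and orange points fell at an adjusted p below 0.05, grey points did not pass, and black bars are list medians. The immediate-early genes reach 4.88 (Fosb), while the lysosomal genes lie on both sides of 0, with a median of -0.11.

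At number 10, pregnancy was compared with pseudopregnancy in the same way, and no gene passed. The smallest p belonged to Hsph1, a heat shock protein gene (chromosome 5, 149614287 to 149636376), at 41.1 ± 0.643 CPM in pregnancy 10 and 79.6 ± 5.99 CPM in pseudopregnancy 10 (log2 fold change -0.95 ± 0.10, adjusted p = 0.312). Chst10, a sulfotransferase gene (chromosome 1, 38863867 to 38898161), stood at 192 ± 47.8 against 72.0 ± 10.001 CPM (log2 fold change 1.41 ± 0.22, adjusted p = 1). Calcoco2, a receptor gene of selective autophagy, had 33 counts in pregnancy 10 (0.468 ± 0.0623 CPM) and 0 in pseudopregnancy 10 (adjusted p = 1). Nr4a3 was at 14.8 ± 8.45 and 2.79 ± 1.74 CPM, and Hbegf, Areg, Pgr and Msx1 had log2 fold changes of 0.04, 0.31, -0.45 and 0.26 (adjusted p = 1 for each of these).

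The count of 0 is edgeR's, while DESeq2 called 15 genes and limma voom 0. Of 20137 genes tested, 701 had an unadjusted p below 0.05, fewer than the share of 0.05 that no effect would give. Camera at the preset correlation called 6 lists, and none with an estimated correlation. The lysosome list was higher in pregnancy, with a median log2 fold change of 0.09 over 57 genes (adjusted p = 0.0271), and so were the vacuolar ATPase list (0.13; 0.00782) and the immediate-early genes (0.27; 0.0253). Mitochondrially encoded mRNAs were lower (-0.53; 1.35e-14), as were the interferon-stimulated genes (-0.27; 0.0126) and leukocyte markers (-0.38; 0.00271). With an estimated correlation the adjusted p = 0.824 for the mitochondrial mRNAs and immediate-early genes and 0.888 for the other 4 lists. Adjusted over the list alone, 4 mitochondrial mRNAs and 1 immediate-early gene passed, and 0 members of the other 4 lists. The lysosome median was 0.21 without pregnancy 10 replicate 1, 0.17 without pseudopregnancy 10 replicate 2, 0.05 without pseudopregnancy 10 replicate 1 (adjusted p = 0.652) and -0.05 without pregnancy 10 replicate 2 (0.735). Without pseudopregnancy 10 replicate 1, 1 gene was called.

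Averaged over both numbers, several immediate-early genes were higher in pregnancy, in an average that includes the number 17 libraries. Nr4a3 rose by 4.16 ± 0.40 on the log2 scale (adjusted p = 0.0159), Nr4a1 by 3.51 ± 0.36, Fosb by 3.38 ± 0.45 and Egr1 by 1.98 ± 0.21, together with Tll1, a metalloprotease of the tolloid family, by 3.24 ± 0.31. The largest falls were those of Slc5a5, the sodium-iodide symporter (log2 fold change -1.91 ± 0.32, from 18.4 ± 4.01 and 10.5 ± 2.89 CPM in pseudopregnancy 10 and 17 to 3.70 ± 0.220 and 3.69 ± 2.59 CPM in pregnancy 10 and 17) and Rec8, a cohesin subunit (-1.42 ± 0.19), then Evl (-0.81 ± 0.12), Tox3 (-0.65 ± 0.11) and Rab3ip (-0.59 ± 0.08). In all, 128 genes passed, 102 higher and 26 lower. The list members that passed were Atp6v0a4 (log2 fold change 2.47 ± 0.25), Atp6v0d2 (1.37 ± 0.19), Ier3 (1.06 ± 0.13), Lifr (1.08 ± 0.16), Per2 (0.57 ± 0.09), Xbp1 (1.18 ± 0.14), Fos (1.62 ± 0.23), Fosb, Egr1 and Nr4a1. All of them rose in the average. Since the average holds the effect at number 17, these calls do not show a rise at number 10, where no gene passed.

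Camera at the preset correlation called 5 lists over both numbers: the immediate-early genes (4 of 15 rose, 10 passed adjusted over the list alone; adjusted p = 1.95e-09), the oestrogen response (0 of 13, 5 adjusted over the list alone; 0.00142), the unfolded protein response (1 of 17, 3 adjusted over the list alone; 0.00142) and cholesterol synthesis (0 of 20, 5 adjusted over the list alone; 0.00508) were higher in pregnancy, and the mitochondrially encoded mRNAs were lower (0 of 12, 0 adjusted over the list alone; 0.00140). With an estimated correlation the adjusted p = 0.173 for the immediate-early genes and 0.760 for the other 4 lists. The lysosome list had 0 of 57 called (3 adjusted over the list alone; median log2 fold change -0.02). The count was 528 with no filter, 51 with the stricter filter, 941 with DESeq2, 26 with voom, and 0 in an additive model of condition and number. Without 1 library it was 61 or 35 (pregnancy 10 replicate 1 or 2), 27 or 665 (pregnancy 17), 3 or 10 (pseudopregnancy 10) and 2 or 42 (pseudopregnancy 17).

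The difference between the effects at 17 and 10 was tested directly, and 42 genes passed, 23 with a higher and 19 with a lower signed log2 fold change at 17. Il6ra, the interleukin 6 receptor (chromosome 3, 89864059 to 89913196), stood at 28.9 ± 6.98 CPM in pregnancy 17 and at 0.790 ± 0.217, 1.17 ± 0.466 and 1.89 ± 0.571 CPM in pregnancy 10, pseudopregnancy 10 and pseudopregnancy 17 (difference of log2 fold changes 4.49 ± 0.52, adjusted p = 0.0263). Depp1 (4.33 ± 0.31), the chemokine gene Cxcl14 (3.78 ± 0.42) and the long non-coding RNA Morrbid (3.79 ± 0.44) had the same pattern, as did Rps24-ps3 (3.98 ± 0.41), a processed pseudogene whose reads cannot be separated from its parent with certainty. Ceacam10, a cell adhesion gene of the CEA family (chromosome 7, 24777206 to 24784657), was at 0.110 ± 0.115 CPM in pregnancy 17 and at 8.35 ± 0.103, 6.56 ± 0.406 and 4.88 ± 1.57 CPM in the other 3 groups (difference -5.77 ± 0.63). Chst10 was the highest in pregnancy 10 and the lowest in pregnancy 17, at 7.04 ± 1.99 CPM (-4.13 ± 0.33, adjusted p = 0.00862), and Mc4r (-5.46 ± 0.72), Grk3 (-3.62 ± 0.48) and Hs3st6 (-3.32 ± 0.43) also passed.

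Camera at the preset correlation called 5 lists for this difference, and none with an estimated correlation (adjusted p = 0.741 for each). The oestrogen response (median difference 0.59, adjusted p = 0.00872), immediate-early genes (0.65; 0.00128), unfolded protein response (0.34; 0.0316) and mitochondrially encoded mRNAs (0.46; 0.0316) were higher at 17, and the lysosome list was lower (-0.22; 0.0316). Adjusted over the list alone 5, 7, 3, 2 and 5 members of these lists passed, and 0 over all genes. The count was 661 with no filter, 1235 with DESeq2 and 7 with voom. Without 1 library it was 12 or 64 (pregnancy 10 replicate 1 or 2), 22 or 931 (pregnancy 17), 6 or 4 (pseudopregnancy 10) and 8 or 28 (pseudopregnancy 17). Across the 20137 genes the pregnancy effects at 10 and 17 correlated with Pearson r = -0.0191 and Spearman rho = -0.0857. Of the 1986 genes called at 17, 898 (45.2%) had the same sign at 10, against 45.5% of all 20137 genes. Genes are not independent replicates, so no test was made.

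Between the title numbers, the pregnancy epithelium changed at 4547 genes, 2217 higher and 2330 lower in pregnancy 17 than in pregnancy 10. Tuba8, a tubulin gene (chromosome 6, 121210696 to 121226854), rose from 0.0978 ± 0.0525 to 31.1 ± 17.1 CPM (log2 fold change 8.24 ± 0.63, adjusted p = 0.000828), Lrat from 0.426 ± 0.389 to 128 ± 20.3 CPM (8.18 ± 0.68), Sftpd by 7.31 ± 0.56 and Fga by 7.28 ± 0.51. Atp13a4, a cation-transporting ATPase gene, rose by 8.17 ± 0.99. Ceacam10 fell 73.2-fold, Mc4r 59.3-fold and Chst10 27.3-fold, and Fam107a (log2 fold change -4.51 ± 1.19) and H60c (-4.43 ± 0.82) fell too.

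In the same comparison 16 of 57 lysosomal genes fell and 4 rose (26 passed adjusted over the list alone; camera adjusted p = 0.0577). Ppt1 (log2 fold change -1.75), Npc2 (-0.85) and Hexa (-0.71) fell, and Lgmn, an asparaginyl endopeptidase, rose by 1.83. Of 20 vacuolar ATPase subunits 3 rose and 4 fell (8 adjusted over the list alone): Atp6v0a4 rose 47.9-fold and Atp6v0d2 by 3.57 on the log2 scale, while Atp6v0a1 (-0.98) and Atp6ap2 (-0.72) fell; the median over the list was -0.20 and the mean 0.33. Receptivity genes had 5 risen and 6 fallen members of 21 (13 adjusted over the list alone), with Lifr up by 2.46, Hbegf by 2.21, Wnt7b by 2.97 and Msx1 at -1.12. Ihh, a progesterone-induced hedgehog ligand, rose from 124 ± 53.9 to 350 ± 61.3 CPM. Of 15 immediate-early genes 7 rose and 1 fell (9 adjusted over the list alone; camera adjusted p = 0.0164), and 5 of 36 ribosomal protein genes fell (1 adjusted over the list alone; 0.000458); with an estimated correlation both had an adjusted p = 0.915. Krt19, Krt8, Krt18 and Cldn3 fell, as 4 of 8 pan-epithelial markers (4 adjusted over the list alone), the stromal markers Dcn (-1.59) and Lum (-1.72) fell, and the endothelial marker Tek rose by 2.44. Without pregnancy 17 replicate 1 the count was 1223; it was 2361 when only the 2 groups were fitted and 2606 with a log2 fold change of at least 1.

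In pseudopregnancy, 17 against 10, 1 gene passed: Hsph1 fell from 79.6 ± 5.99 to 31.4 ± 1.55 CPM (log2 fold change -1.34 ± 0.11, adjusted p = 0.0245). Atp6v0a4 stood at 22.04 ± 1.58 CPM in pseudopregnancy 17 and 3.46 ± 0.567 CPM in pseudopregnancy 10 (log2 fold change 2.67 ± 0.37, adjusted p = 0.184). An unadjusted p below 0.05 was seen for 1464 of 20137 genes, where no effect would give a share of 0.05. DESeq2 called 148 genes, voom 1, and edgeR with no filter 23. With only the 2 groups in the fit 3 genes were called, none of them Hsph1. Among the fits that left out 1 library, Hsph1 was called only where a pregnancy 10 library was left out. It lost its call without any single pregnancy 17 or pseudopregnancy library. Camera at the preset correlation called 9 lists, and none with an estimated correlation: ribosomal proteins (median log2 fold change -0.25, adjusted p = 6.15e-13), mitochondrially encoded mRNAs (-0.62; 1.52e-11), interferon-stimulated genes (-0.60; 3.82e-07), stromal (-0.60; 1.71e-05) and leukocyte markers (-0.63; 0.00149), the unfolded protein response (-0.29; 0.00145) and the proteasome (-0.10; 0.0248) were lower at 17, and the vacuolar ATPase (0.07; 0.00479) and luminal markers (0.38; 0.0383) were higher. With an estimated correlation their adjusted p-values ran from 0.854 to 0.958. Adjusted over the list alone 5 mitochondrial mRNAs, 2 vacuolar ATPase subunits and 1 ribosomal protein gene passed, and 0 members of the other 6 lists.

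The log2 fold changes of 17 against 10 in pregnancy and in pseudopregnancy, which share no library, correlated across genes with r = 0.375 and rho = 0.353. Of the 4547 genes called in pregnancy, 3513 (77.3%) had the same sign in pseudopregnancy, against 62.9% of all 20137 genes. The correlation was 0.170 without pseudopregnancy 17 replicate 2.

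**Figure D4:**
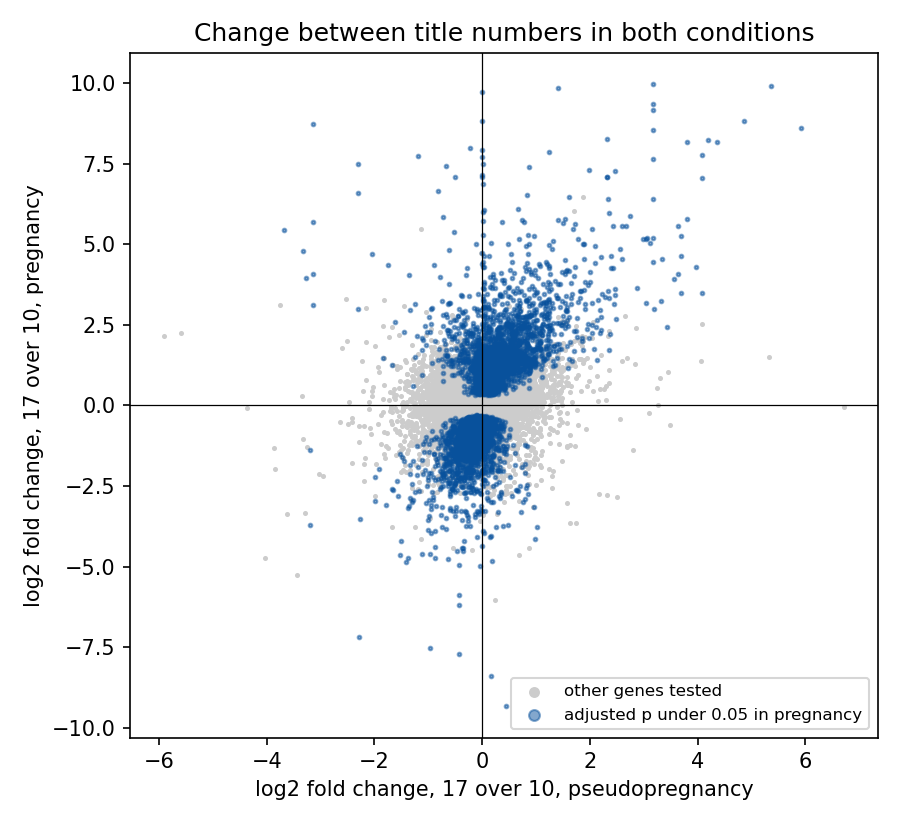
Each point is 1 of the 20137 genes, with the log2 fold change of 17 over 10 in pseudopregnancy on the horizontal axis and in pregnancy on the vertical axis; blue points passed in pregnancy and grey points did not. Of the blue points, 77.3% lie in the quadrants where both fold changes have the same sign.

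The authors' deposited table gives their own folds and unadjusted p-values. A p below 0.05 in the authors' deposited table was seen for 1737 genes between pseudopregnancy and pregnancy at 17 (834 with a fold above 1 and 903 below), 122 at number 10, 3442 between 17 and 10 in pregnancy, and 194 in pseudopregnancy. Of the 1618 of those 1737 genes that were tested here, 1096 were also called, all in the same direction. Both sets of log2 folds come from the same libraries and correlated with r = 0.999999, so the shared direction is no separate evidence. Benjamini-Hochberg adjustment of the p-values in the authors' deposited table left 0 genes below 0.05 in each of the 4 comparisons, where edgeR called 0, 1986, 4547 and 1 here (701, 5453, 7618 and 1464 at an unadjusted p below 0.05, in the order of number 10, number 17, pregnancy and pseudopregnancy).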

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

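The tests of gene length, of stromal tissue in the falling genes, and of rising genes above the stromal markers were chosen after the results they concern had been seen; the other tests of this part were planned before.

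The effect of pregnancy differed between the title numbers, by a test of the difference itself, for 42 genes. These include Il6ra (difference of log2 fold changes 4.49), Depp1 (4.33), Rps24-ps3 (3.98), Morrbid (3.79) and Cxcl14 (3.78), whose signed log2 fold change was higher at 17, and Ceacam10 (-5.77), Mc4r (-5.46), Chst10 (-4.13), Grk3 (-3.62) and Hs3st6 (-3.32), whose signed log2 fold change was lower at 17. By camera at the preset correlation, 5 lists differed between the numbers: immediate-early genes (median difference 0.65), the oestrogen response (0.59), mitochondrially encoded mRNAs (0.46), the unfolded protein response (0.34) and the lysosome list (-0.22). With an estimated correlation none of these 5 lists differed (adjusted p = 0.741 for each). The count of 42 was 931 without pregnancy 17 replicate 2 and 4 without pseudopregnancy 10 replicate 2; the report gives it without each library.

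The 1986 genes that differed between pregnancy and pseudopregnancy at number 17 could in part come from how the tissue was captured or from RNA quality, besides the condition itself. With offsets that remove each library's trend on gene length, 1857 genes were called and 1807 of the 1986 were among them, which argues against a length trend as the whole cause. More stroma in the captured regions would raise no gene above the genes that stroma alone expresses, yet 38.2% of the 1069 risen genes (408) lay more than 2 SE above the highest stromal marker, Thy1 (log2 fold change 1.17). This bound leaves out the spread of Thy1 itself, which did not pass (adjusted p = 0.0613 by edgeR's test). Choosing genes by their call also favours overestimated rises, so 408 may be too many. The bound holds only for tissue like the 12 stromal markers, so other tissue such as endothelium is not excluded for the 408 genes. More stroma would also lower epithelial genes alike, yet 11.01% of the 917 fallen genes (101) lay more than 1 log2 unit and 2 SE below the median pan-epithelial marker (-0.16). Without the margin of 2 SE the share was 32.7%, which an earlier form of this test, with a higher bound, left undecided. The bound was lowered after the data were seen, and the pan-epithelial markers themselves ran from -1.36 (Krt19) to 0.47 (Krt7). The share therefore bears at most on the 101 genes, and stroma stays open for the other fallen genes. Over all 1069 risen genes, the median log2 ratio of replicate 1 to replicate 2 in pregnancy 17 was 0.370 (bootstrap SE 0.0115) against 0.828 (SE 0.0968) for the stromal markers, within the spread of the bound of 0.414. Over the 661 risen genes left after the 408, a set chosen after the data were seen, it was 0.301 (SE 0.0124), which lies 2.26 SE below that bound. These SEs are taken over genes within 1 pair of libraries and hold no spread between libraries. The called falling genes had a median ratio of -0.311, so the ratio also goes with the direction of the change. This comparison therefore does not decide about stroma. A median also does not exclude stroma for part of the 661 genes, and genes that stroma and epithelium share would differ less between the libraries than the stromal markers, so stroma stays open for the 661. The condition stays open as an explanation for all 1986 genes.

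Immediate-early genes were higher in pregnancy 17, and they also respond to handling of tissue. A heat shock in handling would raise heat shock genes too, but the median log2 fold change of 12 of them was -0.0684 (bootstrap SE 0.106), and 1 of them rose (Hspa4l, 1.21). The median of all 15 immediate-early genes was 0.56, with 7 risen and 1 fallen. Handling or delay without heat shock stays open: the 7 risen genes differed between the 2 pregnancy 17 libraries by a median of 0.810 log2 units, all 7 higher in replicate 1, which lies between the values set in advance for and against it. A difference in handling shared by both libraries cannot be told apart from the condition with 2 libraries per group, and the presence of blastocysts stays open and untested.

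For pregnancy against pseudopregnancy over both numbers, all 35 splits of the 8 libraries into 4 and 4 were fitted with a single factor. The real split called 0 genes, the highest other split called 3, and the split by title number called 3, so that all 35 splits called as many genes as the real one. No split could call fewer than 0, so this test says nothing for or against chance. In this fit the title number is not in the model; the fit with 4 groups called 128 genes.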

How the results depend on the processing

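The removal of Gm26917, the gene length offsets with and without the block, and the correlation of 17 against 10 in both conditions were chosen after the data were seen. With no filter on low counts the count of genes was 528 over both numbers, 661 for the difference of effects and 23 for 17 against 10 in pseudopregnancy. The stricter filter gave 51 over both numbers, and a correlation of 0.448 between 17 against 10 in both conditions. DESeq2 gave 15 at number 10, 941 over both numbers, 1235 for the difference and 148 in pseudopregnancy; voom gave 26 over both numbers and 7 for the difference. A log2 fold change of at least 1 left 1236 at number 17 and 2606 for 17 against 10 in pregnancy. With only the 2 groups compared in the fit the counts were 805 at number 17 (739 of them also among the 1986), 2361 for 17 against 10 in pregnancy and 3 in pseudopregnancy. The additive model of condition and number gave 0 over both numbers. The cause of these changes was not tested, except that fewer genes are tested under the stricter filter and fewer libraries are fitted with 2 groups. RLE factors, removal of Gm26917 and length offsets without the block kept each count within 1.5 times.

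The replicate numbers were not taken as pairing the samples, since the labels give no pairing and the correlations of replicate differences between groups were mixed: 0.325, 0.171 and 0.373 among the groups other than pregnancy 17, and -0.164, -0.0623 and -0.177 with pregnancy 17, over 9148 genes. With the replicate number as a block the counts were 37 over both numbers and 19 for the difference; with the block and length offsets they were 35, 17 and, in pseudopregnancy, 0. The block moved no other count by over 1.5 times and changed no call of the lysosome list.

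When each library was left out in turn, counts ran from 0 to 1 at number 10, 68 to 2741 at number 17, 2 to 665 over both numbers, 4 to 931 for the difference, 1223 to 5618 for 17 against 10 in pregnancy and 0 to 2 in pseudopregnancy; a lone library was assumed to vary like the other groups. The median log2 fold change of the lysosome list at number 10 ran from -0.0543 (without pregnancy 10 replicate 2, adjusted p = 0.735) to 0.211. Its value of 0.0902 lost its call with an estimated correlation (adjusted p = 0.888) and with fry (0.927). The correlation of the effects at 10 and 17 ran from -0.0773 to 0.0474, and that of 17 against 10 in both conditions from 0.170 to 0.339; the cause was not tested.

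Of 183 results of named genes that passed, 183 also passed with DESeq2, 182 with no filter, 180 with RLE factors, 180 without Gm26917, 173 with length offsets, 165 with the block, 160 with the block and length offsets and 152 with voom, and between 90 (without pregnancy 17 replicate 1) and 158 with 1 library left out. Of those that other settings could test, 152 of 167 passed with the stricter filter, 114 of 156 with only the 2 groups compared and 0 of 17 with the additive model. In all settings 0 reversed. Among 12812 gene values compared, 163 that passed in neither setting changed sign; they are not counted as reversed, a choice made after these values were seen. List medians changed sign under another scaling in 3 cases with RLE factors and 3 without Gm26917, each at or below 0.00668 in size. In the simulation of number 17, 1.5-fold changes were recovered for 6% of 50 genes. Fewer genes were changed there than the 1986 called in the data, so this share need not hold for the data. Depth was not varied.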

Other observations

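The search through gene families and the test of genes that change with the title number in both conditions were chosen after the results had been seen; the test of genomic DNA and that of the second blastocyst list were written before their results.

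Most of the clustered protocadherin beta genes, cell surface adhesion genes best known from neurons, rose in pregnancy between the title numbers. Of 21 measured, 13 rose and 0 fell from pregnancy 10 to pregnancy 17 (61.9%, against 10.01% of the other genes; Fisher's exact test, two-sided, adjusted p = 1.83e-06 over 184 tests of 92 families), with a median log2 fold change of 1.3015, and 13 rose with RLE factors and without Gm26917 as well. Their summed CPM was 32.9 ± 6.61 in pregnancy 10, 94.1 ± 14.9 in pregnancy 17, 27.8 ± 4.35 in pseudopregnancy 10 and 43.2 ± 11.2 in pseudopregnancy 17 (mean ± SD, n = 2). The myosin family also passed, with 9 of 23 risen (39.1%, adjusted p = 0.0213). At number 17, 3 of the protocadherin genes rose against pseudopregnancy (14.3%, against 5.86% of the other genes; adjusted p = 0.661), and no family passed in that comparison (smallest adjusted p = 0.586, the myosin family included). Members of the protocadherin cluster are close paralogs, so the count of any one is uncertain. Fisher's test treats the members of a family as independent genes. Its p-values therefore do not measure the spread between libraries.

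Genomic DNA in the libraries could raise these genes, which have a single large coding exon, but it would raise the olfactory receptor genes as well. The summed CPM of the olfactory receptor genes had a log2 fold of -0.27 between pregnancy 17 and pregnancy 10, against 1.52 for the protocadherin beta genes, which argues against genomic DNA. The olfactory sums were 20.5 and 11.7 CPM in pregnancy 10 and 12.7 and 14.0 CPM in pregnancy 17. The negative sign therefore rests on pregnancy 10 replicate 1. The title number stays open as an explanation, and what it stands for was not tested.

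A hypothesis from these data is that part of the change from 10 to 17 in pregnancy may also occur in pseudopregnancy. Of the 4547 genes called in pregnancy, 77.3% had the same sign in pseudopregnancy, in separate libraries, against 62.9% of all 20137 genes, and the share was 79.7% or 69.9% without pseudopregnancy 17 replicate 1 or 2. In pseudopregnancy, 1 gene passed by edgeR (1464 at an unadjusted p below 0.05). The libraries of a title number could also share a day of collection or preparation, which the labels do not give, so that the hypothesis stays untested against it.

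Reads of early embryo genes were looked for as a sign of blastocyst RNA in the captured regions. Of the blastocyst list, 12 members were below the filter, and they summed to 93 counts in the 4 pregnancy libraries and 50 in the 4 pseudopregnancy libraries (0.646 ± 0.175 against 0.343 ± 0.109 CPM, exact permutation test, two-sided, p = 0.0571, where the smallest possible p is 0.0286). Over all 15 members the sums, mostly from Elf5, were 16.7, 12.3, 7.67 and 13.0 CPM in the pregnancy libraries. They were 13.0, 14.9, 10.7 and 15.6 CPM in the pseudopregnancy libraries, so the conditions overlapped. Pou5f1 had 9 counts in pregnancy and 0 in pseudopregnancy, Dppa3 7 and 0, Cdx2 6 and 0, and Nanog 5 and 0; these genes were picked after their counts were seen. A second list of 18 genes gave 2.89 ± 2.85 against 1.49 ± 0.180 CPM (p = 0.571, exact permutation test, two-sided), most of it from Esrrb (252 and 105 counts) and Dppa2 (92 and 85 counts). Pregnancy 10 replicate 1 carries the pregnancy mean, with 235 of the 397 counts and 186 of them from Esrrb; without it the mean is 1.47 CPM, against 1.49 CPM in pseudopregnancy. The overlap of the conditions in the second list had been set beforehand as the outcome without embryo RNA, and it was found. That prediction was wrong in taking an overlap to exclude embryo RNA, since Esrrb and Dppa2 also have reads in pseudopregnancy, and this level would hide a small share from embryos. The 16 members below the filter summed to 53 and 28 counts and overlap too (p = 0.2, exact permutation test, two-sided). Of these, Sall4 had 11 and 1 counts, Pramel6 7 and 0, L1td1 5 and 1, and Pramel7 4 and 0, picked after their counts were seen. Gdf3 (19 and 22), Plac1 (0 and 1) and Dnmt3l (0 and 1) went the other way. Embryo RNA is left open.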
